A study of Rattus norvegicus with 12 samples.

How the data were processed

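Liver RNA from 12 obese ZSF1 rats, 6 females and 6 males aged 16 weeks and given no treatment, had been sequenced, 1 library per animal. The ZSF1 rat is a cross of leptin receptor mutant strains, and its obese animals inherit a defective leptin receptor gene from both parents. Libraries were made from 1 µg of total RNA with an Illumina TruSeq RNA kit, per the labels' protocols. The submitters' processing notes name Bowtie2 version 2.0.2, DESeq and the rat build rn4. The counting program, the gene annotation, the strand setting and the treatment of reads that map to several places were not given in the sources used here, so reads of antisense or overlapping genes cannot be told apart.

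The deposited values were whole-number read counts per gene with no normalization, in 16478 rows named by gene symbol that were the same in all 12 libraries. A further 5 rows named no gene. They were reads outside any gene, reads that fit more than 1 gene model, reads that did not align, reads of low alignment quality and reads with no unique alignment. The last 2 rows held 0 throughout, so no read was set aside there as mapping to several places. Whether such reads were counted within genes or removed earlier was not given. The 5 rows held 27.1% to 31.7% of all counts in a library and were left out of library totals and tests. Symbols were looked up in a RefSeq gene table of assembly GRCr8 for names only, and 16256 of 16478 (98.7%) matched. That build differs from rn4, so no coordinates are given. Genes are called by the symbol in the count files.

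Total counts over genes ran from 6763879 to 24837602 in females and from 11381428 to 29232871 in males. At these depths 3 counts correspond to between 0.103 and 0.444 counts per 1000000 (CPM), and values near that level carry large counting errors. Intervals given for genes with few counts are exact 95% binomial intervals of the ratio of summed counts and cover counting error only. No within-sex pair of libraries agreed within sampling noise (chi-square per degree of freedom at least 6.02 over 30 pairs), so each library was counted as 1 animal. The labels give no batch, litter, cage or collection time. Males are numbered 1 to 6 and females 7 to 13, so any batch that followed the animal numbers would coincide with sex.

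The counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10, minimum total count 15) with sex as the group, TMM normalization, and the quasi-likelihood F test with robust dispersion. Adjusted p-values are Benjamini-Hochberg values from this test over the 9943 genes that passed the filter, unless another tool is named. Fold changes are females over males on the log2 scale. The standard error (SE) is the size of the log2 fold change divided by the square root of F. CPM values are scaled by the TMM factors and given as mean ± SD over 6 animals.

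Gene lists, 41 in all, were fixed before the data were examined, together with the tests, the alternatives and the rule for naming genes. The 38 lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01. The correlation estimated per list and fry were reported beside it. Some lists share genes: the P450 list holds 7 tested members of the male-predominant list and 3 of the female-predominant list, and the periportal list shares 4 with the urea cycle and amino acid list. Library totals and shares were compared by 2-sided exact permutation tests over all 924 assignments, whose smallest p is 0.00216.

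The rule named 3 sets of genes. The first was, in each direction, the 12 genes with the largest fold change among those with adjusted p under 0.05, at least 5 CPM in the higher sex and no overlap between the sexes. The second was up to 4 called members of each list with the largest fold change, and its most abundant uncalled member where few were called. The third was every called member of the sex-linked and sex-predominant lists. It gave 170 genes, of which 102 are described, a choice made after their values were seen. Some genes that the rule named are not reported here. Other genes named were also chosen after their values were seen. These are Tef, Arntl and Clock in the clock paragraph, the genes of male 4, female 12 and the male Cish pattern, and Prss1, Prss2, Ins1, Pnlip and Ctrb1 in the last paragraph.

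The edgeR and camera steps were tested on simulated counts for this 6 against 6 comparison, in which 200 genes were set to change among the real genes, 30 others were shifted together as a list, and those that passed the filter were scored. Over the 9901 simulated genes tested, 76.1% of genes changed 1.5-fold, 86.4% of those changed 2-fold and 98.4% of those changed 4-fold were recovered. Of 189 calls, 171 were of these genes, 12 were of the shifted list and 6 were false (3.17%). Counts were drawn independently for each gene, so the simulation could not show how camera behaves where genes are correlated. Far fewer genes were set to change than were called in the real data (4298), so these rates may not carry over.

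The alternatives were DESeq2 size factors, upper quartile factors or library totals in place of TMM, no filter or a mean of at least 1 CPM, the DESeq2 1.42.0 Wald test, limma-voom, no robust dispersion, the 20 most abundant genes left out, an adjusted p under 0.01, and each animal left out in turn. Lists were also run with shared members left out. After seeing the data, fits without male 4 and female 12 together were added, as were the leave-one-out fits for named genes and list members and the correlation estimated per list in such fits.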

Results

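Liver gene counts of 6 females and of 6 males of the obese ZSF1 strain, all 16 weeks old, were compared, which asks how liver transcript levels differ with sex in this obese strain. Female libraries held 15.9 ± 7.53 M counts over genes and male libraries 18.0 ± 6.19 M (SD, n = 6 each; M, 1000000 counts), which did not differ by an exact permutation test (2-sided p = 0.597). The first principal component held 63.4% of the variance and separated the sexes. On the second (11.4%) male 4 stood apart, and on the third (5.84%) female 12 did.

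Female and male livers differed in a large part of their measured transcripts. The sex-predominant P450s were among the widest gaps: Cyp2c12, a female-specific steroid hydroxylase, stood at 6438 ± 479 CPM in females and 101 ± 15 in males, and Cyp2c11, its male-specific counterpart, at 7.92 ± 2.90 in females and 2670 ± 608 in males. Genes of cholesterol and fatty acid synthesis were mostly higher in females. Genes of fatty acid oxidation, bile acid synthesis, the respiratory chain and the ribosome were mostly higher in males. As lists, all 6 of these groups lost their camera call with an estimated correlation (adjusted p from 0.086 to 0.615), and the camera p of the oxidation and ribosomal lists was reached by 18 and 8 of 100 splits of the libraries.

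Of 9943 genes tested, 4298 (43.2%) had an adjusted p under 0.05, 2037 higher in females and 2261 higher in males. Which sex had more calls turned with the scaling, at 2250 and 2030 with upper quartile factors and 2082 and 1987 with library totals, and without male 4, at 2389 and 2238, or male 4 and female 12 together, at 2403 and 2231. The difference was at least 2-fold for 572 of them, 320 higher in females and 252 in males, and at least 8-fold for 38 and 49. Most calls were therefore under 2-fold. Among the called genes 2264 showed no overlap between the 6 females and the 6 males. Over all tested genes 22.8% showed none, where chance gives 0.216%. The median log2 fold change over all genes was -0.013.

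Members of the female-predominant list were called without exception: 13 of 13 tested members were higher in females (camera adjusted p = 1.08e-13, and adjusted p = 0.029 with an estimated correlation). A1bg, an alpha-1-B glycoprotein, was 246-fold higher (log2 7.95, SE 0.573, adjusted p = 8.98e-07). The sulfotransferase Sult2a2 was 16.1-fold higher, the transcriptional coregulator Trim24 14.2-fold, Srd5a1, a steroid 5-alpha-reductase, 6.99-fold, the prolactin receptor gene Prlr 4.55-fold and the fatty acid transporter gene Cd36 3.19-fold. Cyp2c7 differed least of those named, at 1.30-fold. Of the male-predominant list, 19 of 25 tested members were higher in males and 1, Sult1c2, was higher in females (camera adjusted p = 5.12e-17, and adjusted p = 0.029 with an estimated correlation). Sult1c2 had been listed with Sult1c1 as an alternative symbol, and whether both name the same rat gene was not checked. Sult1c3, which was not on the list, was 215-fold higher in males. Cyp4a2 was 18.8-fold, Cyp3a2 14.7-fold, Cyp2c13 8.80-fold, the transporter gene Ust5r 17.8-fold and the reductase gene Dhrs7 173-fold higher in males.

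**Figure D1:**
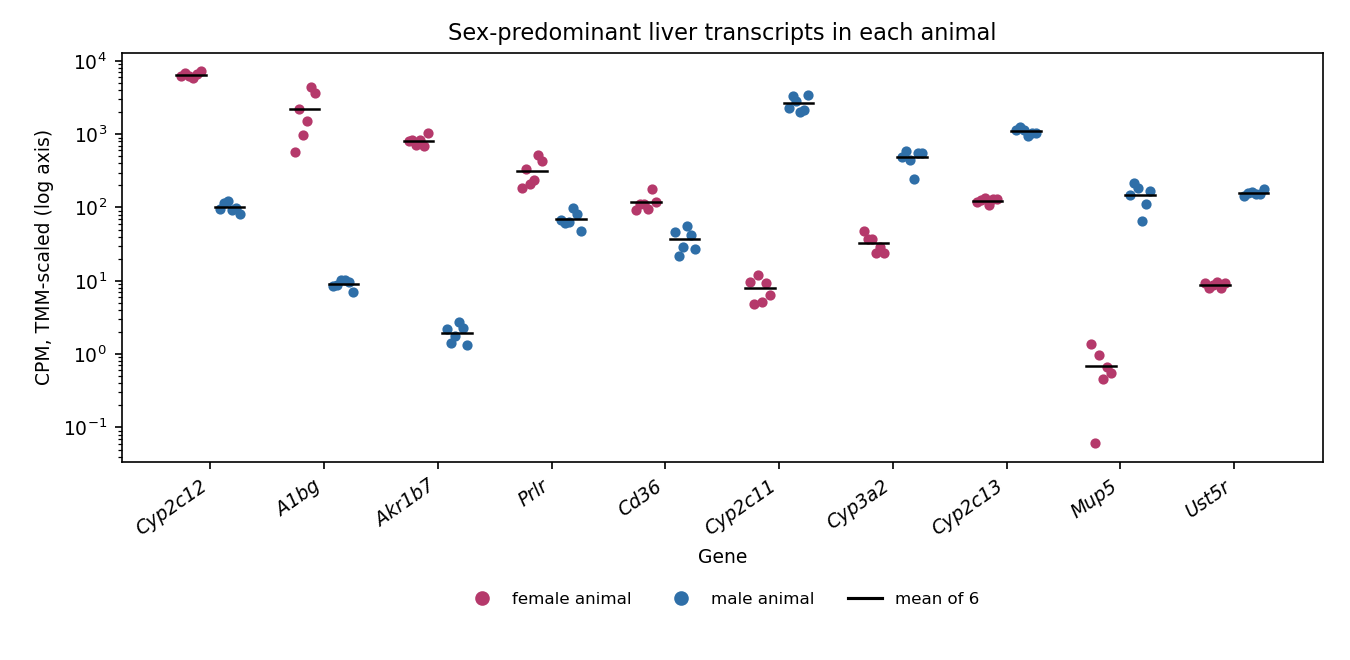
CPM (TMM-scaled, log axis) of 10 sex-predominant genes in each of 6 females and 6 males, 1 point per animal, with the mean as a bar. For each of these genes the points of the sexes do not overlap, as for Cyp2c12 with means of 6438 in females and 101 in males.

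Among the 12 largest differences toward females, the aldo-keto reductase gene Akr1b7 was 427-fold higher (818 ± 122 against 1.95 ± 0.541 CPM), and Akr1b10 was 151-fold higher. Lifr, the leukemia inhibitory factor receptor gene, was 104-fold higher, with a wide spread among females (558 ± 494 CPM), and 68.0-fold with limma-voom. Genes with few counts in males were LOC680227 (ratio 161, counting interval 95.7 to 295), RGD1566112, now named Plekhd1 (109, 55.2 to 254), Scube1 (103, 47.0 to 282) and the transcription factor gene Tox (64.2, 36.5 to 125). The carboxypeptidase gene Cpa1, usually known from pancreas, was higher in females as well, with 3 counts in all males and a ratio of 751 (interval 257 to 3640). Its fitted difference was 524-fold, and 322-fold with limma-voom.

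Among the 12 largest differences toward males were the urinary alpha-2u globulins and 3-beta-hydroxysteroid dehydrogenases. LOC298109 stood at 4250 ± 1610 CPM in males and 16.1 ± 5.14 in females, a 268-fold difference. Mup4 was 321-fold, LOC259244 263-fold, LOC259245 405-fold, Mup5 249-fold and Obp3 245-fold higher, and LOC259246 had 6 counts in females (ratio 430, interval 197 to 1170). Hsd3b5 was 336-fold higher (716 ± 64.0 against 2.38 ± 1.23 CPM). Hsd3b had 3 counts in females (ratio 480, interval 164 to 2330), Hsd3b6 had 1 (ratio 754, interval 135 to 29800) and LOC685099, now named Meiob, had 1 (ratio 510, interval 91.2 to 20200). The fitted log2 fold changes of the last 3, -8.59, -8.79 and -8.23, were -9.68 without female 9, -10.1 without female 12 and -9.56 without female 7 in that order, and with limma-voom they were -7.58 for Hsd3b6 and -7.00 for LOC685099. Members of the alpha-2u globulin family are near-identical in sequence, and the Hsd3b, Akr1b, Sult2a and Cyp2c families also hold related genes. How similar these are was not measured here, so how reads were divided within each family is uncertain.

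The sex labels were checked on linked genes. None of the 8 Y-linked symbols looked up matched a row, so Y-linked genes were not analysed here. Of 4 tested X-linked genes listed for escape from inactivation, 3 were higher in females (camera adjusted p = 0.0171, and adjusted p = 0.317 with an estimated correlation), and 4 of 4 adjusted over the list alone. Whether each of them escapes in rat was not tested here. Eif2s3x was 1.65-fold higher (113 ± 4.74 against 68.3 ± 1.97 CPM), Ddx3x 1.36-fold and Usp9x 1.15-fold, and Zfx, at 10.9 ± 1.45 against 9.16 ± 1.02 CPM, was not called (adjusted p = 0.0641). The Usp9x call (adjusted p = 0.0491) was lost when any of 9 animals was left out.

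Among drug and steroid metabolism genes, those of the P450 list were mostly higher in males. Of 46 tested P450 genes of families 1 to 4, 28 were higher in males and 5 in females (camera adjusted p = 2.42e-06, and adjusted p = 0.029 with an estimated correlation). The sulfotransferase, UDP-glucuronosyltransferase and glutathione transferase genes split, with 19 of 45 higher in males and 12 higher in females, and the list did not differ as a whole (camera adjusted p = 0.687). Sult1c3 was 215-fold and Gstm2 5.43-fold higher in males. Of 20 transporters, 6 were higher in females and 3 in males (camera adjusted p = 0.482). The organic anion transporter gene Slc22a8 was 140-fold higher in males, and the efflux pump genes Abcg2 and Abcb1a were 3.88-fold and 2.43-fold higher in females. Of 16 steroid receptors and converting enzymes, 9 were higher in males and 2 in females (camera adjusted p = 0.0911): Hsd11b1, which regenerates active glucocorticoid, was 6.54-fold and Hsd17b2 2.20-fold higher in males, while the estrogen receptor gene Esr1 was 2.71-fold higher in females.

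Lipid synthesis genes were mostly higher in females. Of 23 cholesterol genes tested, 20 were higher in females and 0 in males (camera adjusted p = 2.44e-09, but adjusted p = 0.245 with an estimated correlation). Sqle, Fdps, Tm7sf2 and Cyp51, enzymes of the sterol pathway, were 3.66-fold, 2.93-fold, 2.88-fold and 2.74-fold higher. Of 21 fatty acid and triglyceride synthesis genes, 13 were higher in females and 1 in males (camera adjusted p = 2.52e-05, but adjusted p = 0.317 with an estimated correlation). Gpam, which starts glycerolipid synthesis, stood at 905 ± 248 CPM in females and 143 ± 46.2 in males (6.33-fold), and Acacb, Elovl6 and Scd were 3.83-fold, 3.62-fold and 3.56-fold higher. In female 12 Elovl6 and Scd stood at 109 and 135 CPM, within the range of the males (64.5 to 137 and 61.8 to 143). The other 5 females averaged 359 and 415 CPM. Gpam and Acacb did not overlap between the sexes.

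Fatty acid oxidation and bile acid genes were mostly higher in males. Of 26 oxidation genes and PPAR-alpha targets, 18 were higher in males and 2 in females (camera adjusted p = 0.000638, but adjusted p = 0.615 with an estimated correlation). Cyp4a3 was 3.46-fold, Vnn1 3.02-fold, Dci, now named Eci1, 2.13-fold and the carnitine palmitoyltransferase gene Cpt1a 1.79-fold higher in males. In female 12 Dci and Cpt1a, at 340 and 281 CPM, lay within the range of the males (254 to 480 and 198 to 318). Cyp4a3 and Vnn1 did not overlap between the sexes. Of 14 bile acid genes, 10 were higher in males and 0 in females (camera adjusted p = 0.000972, but adjusted p = 0.086 with an estimated correlation), among them Nr0b2 (2.79-fold), Cyp7b1 (2.49-fold), Amacr (2.46-fold) and Akr1d1 (2.11-fold). Lipid droplet genes gave 5 of 12 higher in males and 0 in females (camera adjusted p = 0.363), with Plin5 1.58-fold and the lipase gene Pnpla2 1.51-fold higher. Without male 4 these were 4 and 2. Lipoprotein genes gave 8 of 17 higher in males and 3 in females (camera adjusted p = 0.363): Apoa4 was 1.80-fold higher in males and Mttp, which loads lipid onto apolipoprotein B, 1.69-fold higher in females.

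Of 21 glucose and insulin signalling genes, 11 were higher in males and 5 in females (camera adjusted p = 0.171). The leptin receptor gene Lepr was 3.98-fold higher in females (10.5 ± 1.47 against 2.69 ± 0.921 CPM), while Pck1, the gluconeogenic carboxykinase gene, was 3.73-fold (5.74-fold without female 12) and Pfkfb1 2.51-fold higher in males. Of 22 urea cycle and amino acid catabolism genes, 10 were higher in males and 0 in females (camera adjusted p = 0.00177, but adjusted p = 0.361 with an estimated correlation), led by the serine dehydratase gene Sds at 36.3-fold, Gpt at 3.86-fold, Gls2 at 2.14-fold and Got1 at 2.11-fold. Of 17 growth hormone and IGF axis genes, 5 were higher in females and 1 in males (camera adjusted p = 0.314), and 5 and 3 without female 12: Onecut1 was 3.71-fold (6.08-fold with limma-voom), Stat5a 1.66-fold, Stat5b 1.58-fold and Hnf4a 1.49-fold higher in females.

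**Figure D2:**
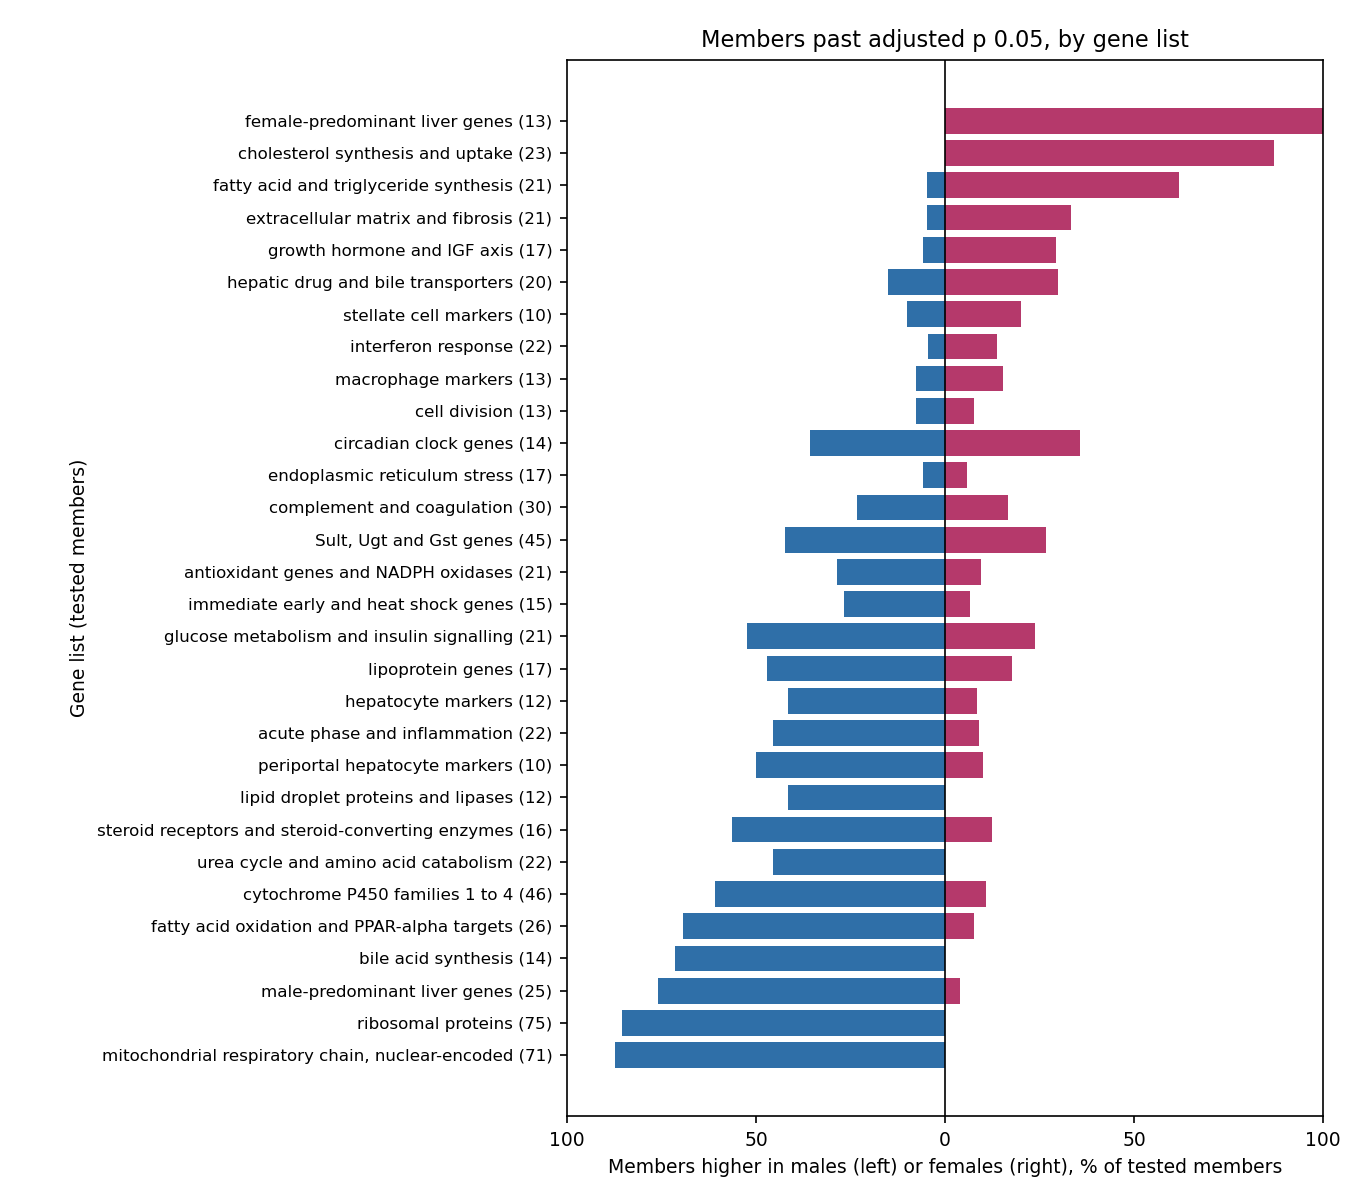
Share of tested members (%) with adjusted p under 0.05 for each list with at least 10 tested members, those higher in males drawn to the left and those higher in females to the right. The number of tested members stands in brackets. Cholesterol genes reach 20 of 23 toward females and respiratory chain genes 62 of 71 toward males.

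Transcripts for the respiratory chain and the ribosome were modestly but broadly higher in males. Of 71 nuclear-encoded respiratory chain genes, 62 were higher in males and 0 in females (median log2 fold change -0.365, camera adjusted p = 1.7e-18, but adjusted p = 0.086 with an estimated correlation). Uqcrq was 1.56-fold and Ndufb3 1.49-fold higher. Of 75 ribosomal protein genes, 64 were higher in males and 0 in females (median -0.303, camera adjusted p = 9.88e-14, but adjusted p = 0.323 with an estimated correlation), with Rpl41 1.53-fold and Rpl37a 1.40-fold higher. Both medians stayed negative under each scaling tried, from -0.337 to -0.365 and from -0.275 to -0.303, while the median of all genes stayed between -0.013 and 0.0152. Measured beside these groups, the 20 most abundant genes took 39.7% ± 1.63 of counts in females and 36.3% ± 0.893 in males (exact permutation p = 0.00433, adjusted over 9 library measures 0.013), and Alb alone took 20.6% ± 2.13 and 16.1% ± 2.31 (exact permutation p = 0.00216, adjusted 0.00972).

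Of 22 acute phase genes tested, 10 were higher in males and 2 in females (camera adjusted p = 0.027, 0.0683 without female 9, and adjusted p = 0.665 with an estimated correlation), and 9 and 3 without male 4. With each animal left out in turn 7 to 11 were higher in males, the fewest without female 7 or 8, and none in females without female 8, 10 or 13 or male 1 or 2. Orm1, an acid glycoprotein gene, was 2.90-fold higher in males (adjusted p = 0.0278, lost without female 7, 12 or 13, and 1.53-fold with adjusted p = 1.79e-05 without male 4), Serpina3n 2.14-fold, the haptoglobin gene Hp 1.86-fold and S100a9 6.15-fold (lost without female 8 or 13, and 2.20-fold without male 4). Male 4 raised the male means of Serpina3n and Hp too. It held 7390 and 30700 CPM, the other 5 males 3720 ± 383 and 11200 ± 593, and the females 2020 ± 273 and 7778 ± 408. Male 4 held 9560 CPM of Orm1 where the other 5 males held 1520 ± 94.4, and 269 CPM of Lcn2, the lipocalin 2 gene, where they held 2.47 ± 1.2. Complement and coagulation genes gave 7 of 30 higher in males and 5 in females (camera adjusted p = 0.482), and 8 each without male 4. Interferon response genes gave 3 of 22 higher in females and 1 in males (camera adjusted p = 0.375), and 6 and 3 without male 4. No interferon gene was higher in males without any 1 of females 7, 9, 10, 12 and 13 and males 1, 2, 3, 5 and 6.

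**Figure D3:**
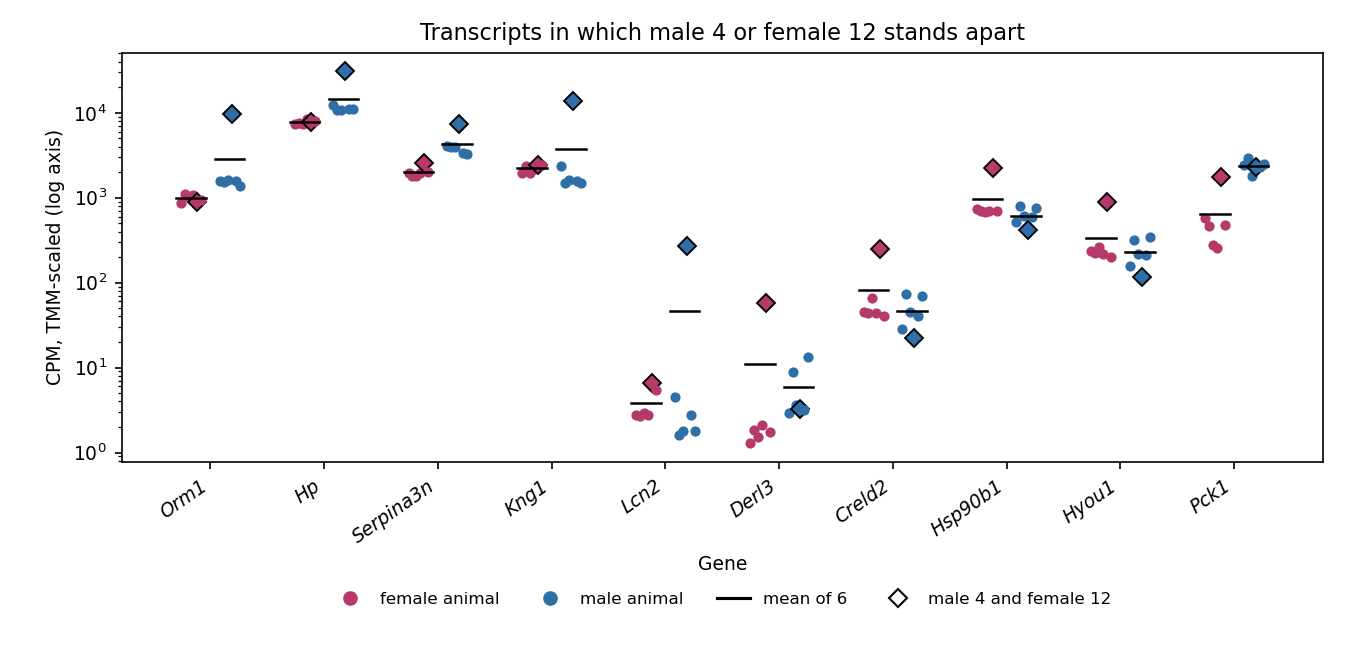
CPM (TMM-scaled, log axis) of 10 genes in each of 6 females and 6 males, 1 point per animal, with the mean as a bar and male 4 and female 12 as diamonds. Male 4 lies above the other males for Orm1, Hp, Serpina3n, Kng1 and Lcn2, at 9560 CPM for Orm1, and female 12 above the other females for Derl3, Creld2, Hsp90b1, Hyou1 and Pck1.

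Counts of called matrix genes and macrophage markers depended on male 4. Of 21 extracellular matrix genes, 7 were higher in females and 1 in males (camera adjusted p = 0.0463, but adjusted p = 0.665 with an estimated correlation), and 14 and 0 without male 4. The camera call was lost without any 1 of females 8, 12 and 13 and males 1, 3, 5 and 6 (adjusted p from 0.0588 to 0.109) and with the filter at a mean of 1 CPM (0.0552). Without other animals than male 4, 5 to 8 were higher in females. Loxl2 was 2.32-fold and Col5a1 1.54-fold higher in females. Dcn was 1.96-fold higher in males, a call (adjusted p = 0.0436) lost when any of 9 animals was left out. Of 13 macrophage markers, 2 were higher in females and 1 in males (camera adjusted p = 0.125), and 11 and 0 without male 4 (camera adjusted p = 0.000216, but adjusted p = 0.426 with an estimated correlation). Without female 12, male 1 or male 6 they were 1 and 0. The Kupffer cell marker Clec4f was 1.69-fold and Cd163 1.81-fold higher in females, the latter lost when any of 5 animals was left out. Of 7 sinusoidal endothelial markers, 6 were higher in females (camera adjusted p = 0.00852, but adjusted p = 0.501 with an estimated correlation), with Flt4 2.74-fold and Fcgr2b 2.39-fold higher.

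Hepatocyte markers gave 5 of 12 higher in males and 1 in females (camera adjusted p = 0.0814, and 0.0326 without male 4 and female 12 together), pericentral markers 4 of 9 higher in females and 1 in males (0.0555), and periportal markers 5 of 10 higher in males and 1 in females (0.0593). The pericentral list was called without female 8, male 5 or male 6 (0.0469, 0.0326 and 0.0327) and the periportal list without female 12 or 13 (0.0322 and 0.0483), and with an estimated correlation none of these lists was called in those fits (adjusted p at least 0.179). The hepatocyte marker higher in females was lost without any 1 of females 10, 12 and 13 and males 1, 2 and 3. Of the 12 hepatocyte markers 7 were themselves among the 20 most abundant genes, and with those genes left out 1 marker was higher in males and 0 in females. Oat, an ornithine aminotransferase gene of pericentral cells, was 5.94-fold higher in females. Stellate cell markers gave 2 of 10 higher in females and 1 in males (0.88), bile duct markers 1 of 5 higher in males (0.417; 2 without female 9), and adipocyte markers 1 of 4 each way (0.837). The adipocyte marker higher in males was lost without any 1 of females 7, 10, 12 and 13 and males 3, 4 and 5, and 2 were higher in females without male 4. Erythroid markers gave 3 of 5 higher in males (0.295), Hbb among them at 1.74-fold, 0 without male 4, female 9 or female 12, and 1 without female 7, 8 or 13 or male 2. Without female 12 or male 2, 1 was higher in females. The Hbb call was lost without female 9, female 12 or male 4. No lymphocyte marker of 8 was called by edgeR (0.837), 1 was higher in females without male 4, and 1 higher in males without male 1, 2, 3 or 6. Of 5 tested pancreas markers 2 were higher in females, Cpa1 among them, and 1 in males, Cela1, a chymotrypsin-like elastase gene, at 4.17-fold (0.427). The neutrophil and kidney lists had 1 tested member each.

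Clock genes divided, with 5 of 14 higher in females and 5 higher in males (camera adjusted p = 0.95, fry adjusted p = 1.33e-05 for change in either direction), and 5 and 4 without male 4. That fry test called 31 of the 38 tested lists, so its result does not set the clock list apart. Dbp, a clock output gene, was 8.21-fold higher in males (56.1 ± 29.9 against 7.07 ± 4.69 CPM), Nr1d1 3.01-fold, Per3 2.47-fold and Tef 2.16-fold, while the activator genes Npas2, Arntl and Clock were 2.66-fold, 1.89-fold and 1.79-fold higher in females. The hour of collection was not given in the sources used here. Antioxidant genes and NADPH oxidases gave 6 of 21 higher in males and 2 in females (camera adjusted p = 0.47), and 6 each without male 4. The oxidase gene Nox4 had 5 counts in females (ratio 69.5, interval 29.5 to 215; fitted log2 fold change -5.85, and -6.58 without female 13), the catalase gene Cat was 1.38-fold higher in males, and Nfe2l2, a regulator of antioxidant genes, 1.41-fold higher in females. Immediate early and heat shock genes gave 4 of 15 higher in males and 1 in females (0.379), endoplasmic reticulum stress genes 1 of 17 each way (0.702), and cell division genes 1 of 13 each way (0.925). The stress gene higher in females was lost without male 1, 2, 3, 4 or 5, and 3 were higher in males without female 12. The cell division gene higher in males was lost without female 7, 8, 10 or 13 or male 1, 2 or 3, the one higher in females without female 10, and 2 were higher in females without male 1.

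**Figure D4:**
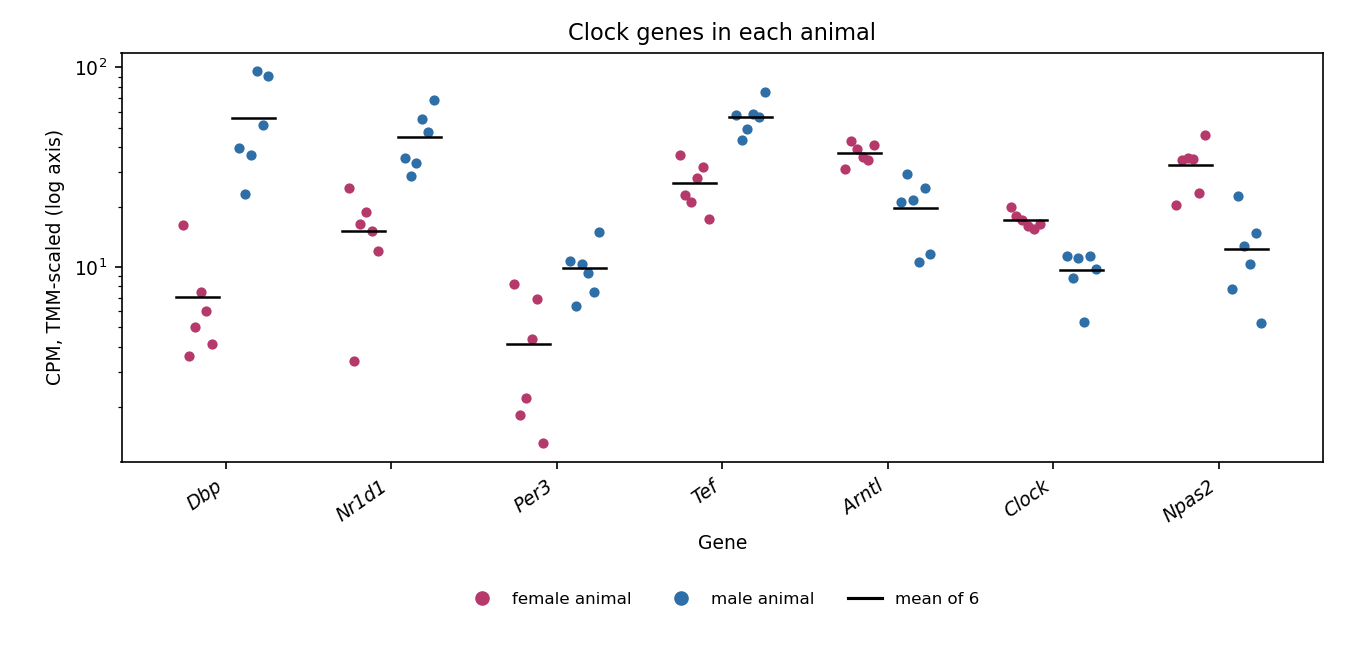
CPM (TMM-scaled, log axis) of 7 clock genes in each of 6 females and 6 males, 1 point per animal, with the mean as a bar. Output genes such as Dbp (means 7.07 and 56.1) sit higher in males and activator genes such as Clock (means 17.2 and 9.64) higher in females.

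By camera, 14 of the 38 tested lists had an adjusted p under 0.05, 6 toward females and 8 toward males. With an estimated correlation 3 held: the male-predominant, female-predominant and P450 lists. Of 100 splits of the 12 libraries into 6 and 6, the real one included, 28 gave at least 14 camera calls, while only the real one gave as many called genes. By fry, 21 lists changed on balance one way and 31 in either direction. Both the median and the mean differed in sign from the camera direction for the clock, stellate and cell division lists, and the mean alone did for the transporter list. Camera called none of these lists. Adjusted over the list alone, the members higher in females and in males were 1 and 20 for the male-predominant list, 7 and 29 for P450s, 13 and 19 for conjugation enzymes, 14 and 1 for fatty acid synthesis, 4 and 8 for lipoproteins, 5 and 12 for glucose, 4 and 1 for the growth hormone axis, 5 and 9 for steroid genes, 0 and 63 for the respiratory chain and 0 and 68 for the ribosome. They were 5 and 1 for pericentral, 1 and 0 for macrophage, 1 and 4 for erythroid, 3 and 0 for interferon, 0 and 1 for endoplasmic reticulum stress and 0 and 0 for cell division genes, and for the other lists they equalled the counts over all genes, the X-linked list apart.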

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

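All tests of male 4 in this part were chosen after the result was seen, as was the growth hormone test. The tests of other splits, of library depth and of overlapping gene models were written before their own results were seen. The depth test concerns the male Cish pattern, whose genes were picked from these data, so the pattern itself was not set beforehand. An animal was singled out where its gap to the nearest of its own sex was larger, as a share of the range of the 6, than Dixon's 95% critical value. Of 214 groups of 6 examined this way, 26 had such an animal, where chance gives about 10.7. Male 4 held 10 of them and female 12 held 7. The chance figure assumes independent groups with normal spread. The same 12 animals recur in these groups, and the genes were named from their values in these data, so the excess over 10.7 is no test of outlying animals.

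Other splits of the 12 libraries bear on the counts of calls. Of 100 of the 462 possible splits into 6 and 6, only 1, the real one, gave as many as 4298 genes, and the highest of the others, which kept 5 females together, gave 813. In 98 of them no gene was called. The rank of the real split argues against a random grouping of the libraries as the source of the gene count. Every other split mixes females and males, which adds the sex difference to the spread within groups. Splits with no call therefore do not measure how many genes would be called without a sex difference. For the 14 lists called by camera the splits cannot decide. Of the 100 splits, 28 gave as many, the highest of the others gave 18, and the median of the others was 11. A split with more females on one side still carries part of the sex difference, as did the one with 18 lists, which kept 4 females together. Chance is thus not excluded for the number of lists, and counts list by list share this limit. Taken list by list, a comparison added after the count of 28 was seen, 7 of the 14 had a camera p that fewer than 5 of the 100 splits reached. These were the male-predominant, female-predominant, P450, cholesterol, fatty acid synthesis, bile acid and respiratory chain lists. The X-linked (7 of 100 splits), ribosomal (8), urea cycle (13), oxidation (18), sinusoidal endothelial (22), matrix (44) and acute phase (59) lists were reached more often. With an estimated correlation the real split gave 3 lists and the highest other 1.

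In male 4, acute phase transcripts were far above those of the other males: Orm1 at 9560 CPM (others 1360 to 1600), Hp at 30700 (10900 to 12300), Serpina3n at 7390 (3250 to 4070) and S100a9 at 14.1 (0.98 to 1.75). The scaling of that library is argued against by the gap between the median deviation of the acute phase list, 0.91 on the log2 scale, and that over all genes, -0.0071. TMM scaling holds the median over all genes near 0 in any library, so that value alone carries no weight. A single factor for the library would move both medians alike. Neutrophils as the source of Orm1, Hp and Hpx are argued against too, because the rise of S100a8 and S100a9 was 0.0552% of theirs. A mislabelled female library is argued against by the 19 male-predominant genes called higher in males, whose mean log2 CPM was 8.33 (other males 8.80 to 9.27, females 2.78 to 3.63). Those calls counted male 4 as a male, and without male 4 the number of such calls was 19 as well. Macrophage markers also rose there (median deviation 1.40), so other leukocytes stay open as a source of Lcn2 and S100a9, and no biological explanation other than cells of another type was tested.

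Among the males Cish, Socs2 and Onecut1, targets of growth hormone signalling, varied together, with Cish from 0.91 CPM in male 6 to 61.0 in male 2. Over the 6 males r was 0.818 for Cish with Socs2, 0.881 for Cish with Onecut1 and 0.922 for Socs2 with Onecut1 (rho 0.771, 0.829 and 0.771, exact permutation p from 0.0208 to 0.0403 for r and from 0.0583 to 0.103 for rho, adjusted 0.0604 and 0.154 over 6 relations), and without the 2 farthest males 0.862, 0.86 and 0.819. Library depth is argued against only weakly, and for Cish alone: its rank correlation with total counts was 0.0286 over 6 males (exact permutation p = 1, r = -0.364 with exact permutation p = 0.489). Without the 2 males farthest in depth r was 0.899, and Socs2 and Onecut1 were not set against depth, so depth is not excluded. A growth hormone pulse that reached some males before collection may be a candidate explanation, with a median r of 0.881. It stays open because these genes were picked for the pattern, no r passed the adjustment, and no hormone level was used here.

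Reads that fit more than 1 gene model, which no comparison used, made up 1.74% ± 0.337 of all counts in males and 0.376% ± 0.0119 in females (exact permutation p = 0.00216, adjusted 0.00972). Overlapping alpha-2u globulin gene models are a candidate explanation. Over the 6 males the share rose with the summed CPM of 8 alpha-2u globulin genes (r = 0.995, exact permutation p = 0.00139, adjusted 0.00834; rho = 1, exact permutation p = 0.00278, adjusted 0.0167), and r was 0.982 without the 2 farthest males. These genes held 7018 ± 2620 CPM in males and 29.0 ± 9.50 in females. Whether their own counts lack such reads was not tested.

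The remaining animals that stood apart are given as values. In male 4, Cyp3a2 was 241 CPM (other males 450 to 597), Pfkfb1 18.3 (43.7 to 64.1), Hsd3b6 6.64 (7.98 to 8.67), Rpl41 196 (164 to 168) and Pnpla2 64.4 (40.8 to 46.2), and Alb took 11.6% of counts (16.3 to 17.8). In female 12, Dci was 340 CPM (other females 135 to 178), Serpina3n 2540 (1790 to 2020), Gpt 82.4 (108 to 123), Got1 93.2 (78.3 to 83.0), Mttp 655 (449 to 510) and Plin5 6.24 (3.27 to 3.60). In female 9, Hnf4a was 141 CPM (174 to 190), Esr1 12.3 (17.7 to 21.8), Zfx 13.7 (9.64 to 10.8) and Clec4f 57.8 (76.9 to 86.0). In female 7, Cpa1 was 2.37 CPM (13.9 to 36.1) and Ddx3x 375 (310 to 330), and in female 8 Nr1d1 was 3.40 (12.1 to 25.0). Single counts lie behind Hsd3b6 at 0.0752 CPM in female 12 and LOC685099 at 0.0988 in female 7, and Hsd3b was 0.277 in female 9.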

How the results depend on the processing

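The fits without male 4 and female 12 together, and those that leave out animals for named genes and list members, were chosen after seeing the data. The gene count stayed within 1.5 times of 4298 under every alternative run, from 2924 at an adjusted p under 0.01 to 4634 without male 4 and female 12. At an adjusted p under 0.01 the genes higher in females fell to 1353, since fewer pass a stricter threshold. With a correlation estimated per list 3 lists were called, and the cause was not tested beyond the estimate itself. Leaving out 1 animal at a time gave 3855 to 4627 genes, 1810 to 2389 higher in females, 2019 to 2238 higher in males, 573 to 631 with a 2-fold difference and 13 to 15 lists. Of the 4298 genes, at least 88.4% were called again under each other fit at the same threshold, with 0 of opposite sign. Of the 102 named genes 95 kept their call with each of the 12 animals left out, and none changed sign under any alternative run. The 7 that did not were Usp9x, Zfx, Orm1, S100a9, Cd163, Hbb and Dcn. Usp9x and Dcn lost their calls under library totals and without a filter, Usp9x without robust dispersion, Hbb and Usp9x without male 4 and female 12, and S100a9 under limma-voom. Zfx was called with upper quartile factors, with the filter at 1 CPM and without male 3, each taken alone. DESeq2 gave no adjusted p for Orm1 and S100a9. The 50 most abundant genes differed between the sexes as the 20 did. Depth limits the genes with few counts in one sex.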

Other observations

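The genes in this part were chosen after their values were seen. Female 12 differed from the other females in genes of protein folding in the endoplasmic reticulum. Derl3 stood at 57.7 CPM where the other 5 females held 1.70 ± 0.318, Creld2 at 250 (48.1 ± 10.1), Hyou1 at 886 (228 ± 25.0), Sdf2l1 at 93.9 (24.6 ± 1.97) and Hsp90b1 at 2230 (698 ± 21.1). The median deviation of the endoplasmic reticulum stress list was 1.03 on the log2 scale in this animal and between -0.423 and 0.453 in each of the others. Pck1 (1740 against 413 ± 141) and Igfbp1 (69.6 against 9.40 ± 4.96) were higher there, and Cyp7a1 (29.6 against 122 ± 38.6) was lower. Without female 12, 3 endoplasmic reticulum stress genes were higher in males and 1 in females.

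Some genes deviated widely in male 4 and were picked for that. RT1-Bb stood at 25.4 CPM (other males 2.84 ± 0.411), RT1-Ba at 59.2 (7.14 ± 0.882), RT1-Db1 at 80.1 (9.91 ± 1.78), Mt1a at 212 (23.0 ± 12.5) and Mt2A at 113 (10.7 ± 6.02). The kininogen gene Kng1 stood at 13800 CPM (1700 ± 376). In the other direction Mx2 was at 5.71 (28.4 ± 3.75) and Oas1a at 2.41 (10 ± 1.60), both interferon-induced genes. In male 4, 650 of 9943 genes deviated by more than 1 on the log2 scale from the mean of the other males, against 36 to 238 in each other animal.

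The pancreas symbols did not move together. Cpa1 held 2002 counts in females and 3 in males, while Prss1, Prss2 and Ins1 had 0 counts in all 12 libraries, Pnlip 1 and Ctrb1 4 in females and 6 in males.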
